A study of Mus musculus with 8 samples.

How the data were processed

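Poly(A) RNA from mouse Tregs on day 6 of culture was made into libraries with a strand-marking Illumina TruSeq mRNA kit, per the labels' protocols. TopHat2, SAMtools, HTSeq, DESeq2 and the build GRCm38.p4 are named in the submitters' processing notes, with no role or order. The annotation release and the strand setting of the counting are not given in the sources used here, so for the 15 named genes with an annotated gene on the opposite strand (Foxp3, Ikzf2 and Cd27 among them) reads of the overlap may be shared. Counts of near-identical genes, such as Trbc2 with its paralog and the ribosomal protein genes with their pseudogenes, are uncertain too, since their reads can map to several genes.

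The deposited table holds 19703 genes. Its library columns are a signal that the authors made by dividing each gene's read count by 1 size factor per library, and its mean column is the authors' mean of that signal over 8 libraries, as the values show. In each column every value was a whole multiple of 1 step (100% within 0.01 of a whole number), so the reads were recovered exactly. The table also gives the authors' log2 fold change with its standard error, a deposited score (the Wald statistic) and deposited p-values, all from DESeq2 per the file headers. The authors' fold changes are coded as untreated minus FcCD70, and their sign was turned wherever one is printed. The sample titled FcCD70 and numbered 4 had no column in the table used here. Its values follow from the mean over 8 libraries, and this rebuilt library (21031069 reads) entered only alternatives chosen after seeing the data.

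Groups follow the sample titles, because the treatment field says the opposite of the title in all 8 samples. Column names go with the titles. The replicate number entered as a block, since the authors' table is named as a paired analysis. Over the 7 libraries with a column, the untreated library numbered 4 then has no partner. Fold changes with the block therefore rest on the 3 same-numbered pairs, with 2 residual degrees of freedom. Leaving out the libraries numbered 1, 2 or 3 leaves fewer pairs and 1 residual degree of freedom. The p-values of those block fits rest on little replication. A DESeq2 fit on 8 libraries with the number as a term gave log2 fold changes with a correlation of 0.99997 across 14728 genes to the authors' (median absolute difference 3.58e-05), against 0.881 (median 0.0161) without it. The plan had named 8 samples and read counts as one possible unit. As the values were not counts, the planned test for other units was used, limma (3.58.1, with a trend) on log2(value + 1), over genes with a mean normalized count of at least 10, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates those of low genes. Limma fits on 7 and 8 libraries, with and without the block, with the covariate and without the FcCD70 library numbered 2, had been looked at before the 7 libraries with a column were kept for the results. Those with the block over all libraries called 0 genes.

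Gene lists (29, with 486 distinct genes, of which 438 had a row) were fixed before the data were examined and tested with camera, with a preset correlation of 0.01, and with fry. The 27 lists with a tested member were adjusted together. With fry 0 lists passed. The lists cover T cell programs (Th17, Treg, Th1 and cytotoxic, Th2, Tfh), signalling, metabolism, proliferation and markers of other cells. Named genes were fixed by the same plan. They are the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 50 and no gene model, pseudogene or receptor segment name, or all if fewer than 10 passed (none did), then Foxp3, Il17a, Il17f, Il22, Il23r, Ccr6, Il1r1, Il2ra, Ctla4, Ikzf2 and Cd27 whatever their result, and up to 2 members of each list in each direction past the threshold or, where none passed, the member with the smallest p. Some genes that this rule takes are not reported here. Other genes were chosen after their values were seen.

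The tests were tried on simulated reads drawn for the 11083 genes from the means of these 7 libraries, each gene independently of the others, which the real libraries do not show, and with the changed genes taken from those with fitted means over 50. For this comparison limma recovered 129 of 335 genes changed 1.5-fold, 292 of 335 changed 2-fold and 330 of 330 changed 4-fold, and called 56 of 54415 unchanged genes. Every simulated table held changed genes of each size at once, which loosens the adjusted threshold, and no library was made to stand apart. These shares may therefore overstate what could be found in the real libraries. With the Th17 list lowered by a log2 value of -0.3 in 20 simulated tables, camera with the preset correlation called it in 20 and with an estimated correlation in 0, so in these simulations the estimated correlation missed a shift of that size.

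Each library's depth sets its floor: 3 reads, which is 0.128 to 0.165 RPM in the 7 libraries, and covers counting error only. Alternatives were the fit without the block, quantile normalization, no filter, other pseudocounts, thresholds and backgrounds, and leaving out libraries, as planned. Added after seeing the data were edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads, 8 libraries, the numbers 1 and 2 against 3 and 4 as a covariate (without the FcCD70 library numbered 2 also with an estimated correlation), and values with the trend on transcript length and GC content removed. Coordinates, lengths and GC content came from GENCODE M21 on GRCm38, in which 19615 of the gene IDs matched. R was version 4.3.3 and Python 3.11.15.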

Results

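Regulatory T cells (Tregs), the CD4 T cells that carry the transcription factor FOXP3 and restrain immune responses, were sorted from FOXP3-GFP reporter mice. They were cultured with beads that engage CD3 and CD28 and with IL6, IL23 and IL1B, cytokines that favour the IL-17-producing Th17 fate. Some cultures also received FcCD70, a soluble form of CD70, the ligand of CD27, a costimulatory receptor of the TNF receptor superfamily. Messenger RNA was sequenced on day 6. The question was what CD27 signalling does to the transcriptome of Tregs under Th17-favouring conditions. The labels name 4 samples of each kind, and 7 of the 8 have a column in the table used here (4 titled untreated, 3 titled FcCD70). The titles and the treatment field contradict each other in all 8 samples, so groups follow the titles, with which the column names go, and every direction below holds only if the titles are right. The untreated libraries numbered 1 to 4 held 18159685, 19715108, 21200214 and 23527899 reads assigned to genes, and the FcCD70 libraries numbered 1 to 3 held 19247437, 18183470 and 23359331. Nothing in the labels says that the samples came from separate mice, so p-values measure the spread between these samples, which may be technical.

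Genes of the Th17 program were lower in the FcCD70 libraries. Of 22 measured members of this list, 20 had a negative log2 fold change and 2 a positive one (Sgk1 and Hif1a, named after their values were seen), and the median was -0.31. The list passed limma's camera test with a preset correlation of 0.01 (adjusted p = 1.45e-05 over 27 lists), and with an estimated correlation it did not (adjusted p = 0.847 with an estimated correlation). No member passed the threshold over all genes tested, and 1 (Il17f) passed when adjusted over the list alone. The list's median difference was -0.37 between the libraries numbered 1, -0.29 between those numbered 2 and -0.09 between those numbered 3. Between those numbered 4, with the rebuilt FcCD70 library, it was -0.096, so the larger differences lay in the numbers 1 and 2. With the replicate block and the preset correlation, the list passed camera without the libraries numbered 1 (adjusted p = 0.00624, median -0.25). It also passed without those numbered 2 (adjusted p = 1.52e-05, median -0.24) or 3 (adjusted p = 0.000381, median -0.32). Each of these fits rests on fewer pairs, with 1 residual degree of freedom. When single libraries were left out in a fit without the replicate block, the call was lost without the untreated library numbered 1 (adjusted p = 0.215, median -0.12) and without the FcCD70 library numbered 3 (adjusted p = 0.561, median -0.12).

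Il17f, a cytokine of the IL-17 family (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617, GRCm38), stood first among all genes by unadjusted p. Its normalized count was 412 ± 223 (SD, n = 4) in the untreated libraries and 189 ± 147 (SD, n = 3) in the FcCD70 libraries, with a log2 fold change of -1.57 (SE 0.27, 95% interval -2.18 to -0.96). It was lower with FcCD70 in 3 of 3 same-numbered pairs, although the ranges of the groups overlapped, and its adjusted p over all genes was 0.9998 in limma. With the block the untreated library numbered 4 does not enter the fold change, which was also -1.57 without that library. In the authors' deposited DESeq2 table, over 8 libraries, Il17f had an adjusted p of 0.211 and a log2 fold change, turned to FcCD70 minus untreated, of -1.19. DESeq2 on the recovered reads of the 7 libraries called it (adjusted p = 0.00159), and edgeR did not. DESeq2 refitted to 8 libraries, the rebuilt one included, with the number as a term, called 0 genes. Limma without the FcCD70 library numbered 2 called Il17f, with a covariate in place of the block (adjusted p = 3.26e-05). With the rebuilt eighth library added to that fit the call was lost (adjusted p = 0.329, log2 fold change -1.36), and the pair numbered 4 had 248 and 229 normalized counts. Limma with the block called Il17f without the libraries numbered 3 (adjusted p = 0.0180), which leaves the pairs numbered 1 and 2. It also did so with the length and GC content trend removed (adjusted p = 0.0430), a fit chosen after seeing the data. Over the alternatives the adjusted p of Il17f ran from 9.30e-11 to 0.99998. The former, in limma without the libraries numbered 2, rests on the pairs numbered 1 and 3, with 1 residual degree of freedom. The latter came without the FcCD70 library numbered 2, with neither block nor covariate. The sign of Il17f was the same throughout. Its log2 fold change lay below 0 in each, from -2.02 without the FcCD70 library numbered 2 to -0.53 without the one numbered 3, the latter in a fit without the block. That fit leaves only the numbers 1 and 2 in the FcCD70 group, against 1 to 4 in the untreated group.

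Other genes of the Th17 lineage had smaller differences, none past the threshold. Il17a, the neighbouring IL-17 cytokine gene (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), had 114 ± 60.3 (SD, n = 4) normalized counts untreated and 53.5 ± 28.6 (SD, n = 3) with FcCD70, and was lower in 3 of 3 pairs. The receptor genes Il23r, Ccr6 and Il1r1 had log2 fold changes of -0.68, -0.41 and -0.33, with lower values in 2, 2 and 3 of 3 pairs. With the block and the libraries of any 1 number left out, they stayed negative, at -1.13 to -0.36, -0.61 to -0.14 and -0.49 to -0.11. Without the block 1 library could turn each: Il23r had 0.09 without the untreated library numbered 1, Ccr6 0.03 without the FcCD70 library numbered 2, and Il1r1 0.25 without the FcCD70 library numbered 3. For Il23r and Il1r1 those fits do not balance the numbers 1 and 2 against 3 and 4 between the groups. Il22 was near the limit of detection, with 3.48 normalized counts in 1 untreated library, 4.41 in 1 FcCD70 library and 0 in the other 5, and was not tested.

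**Figure D1:**
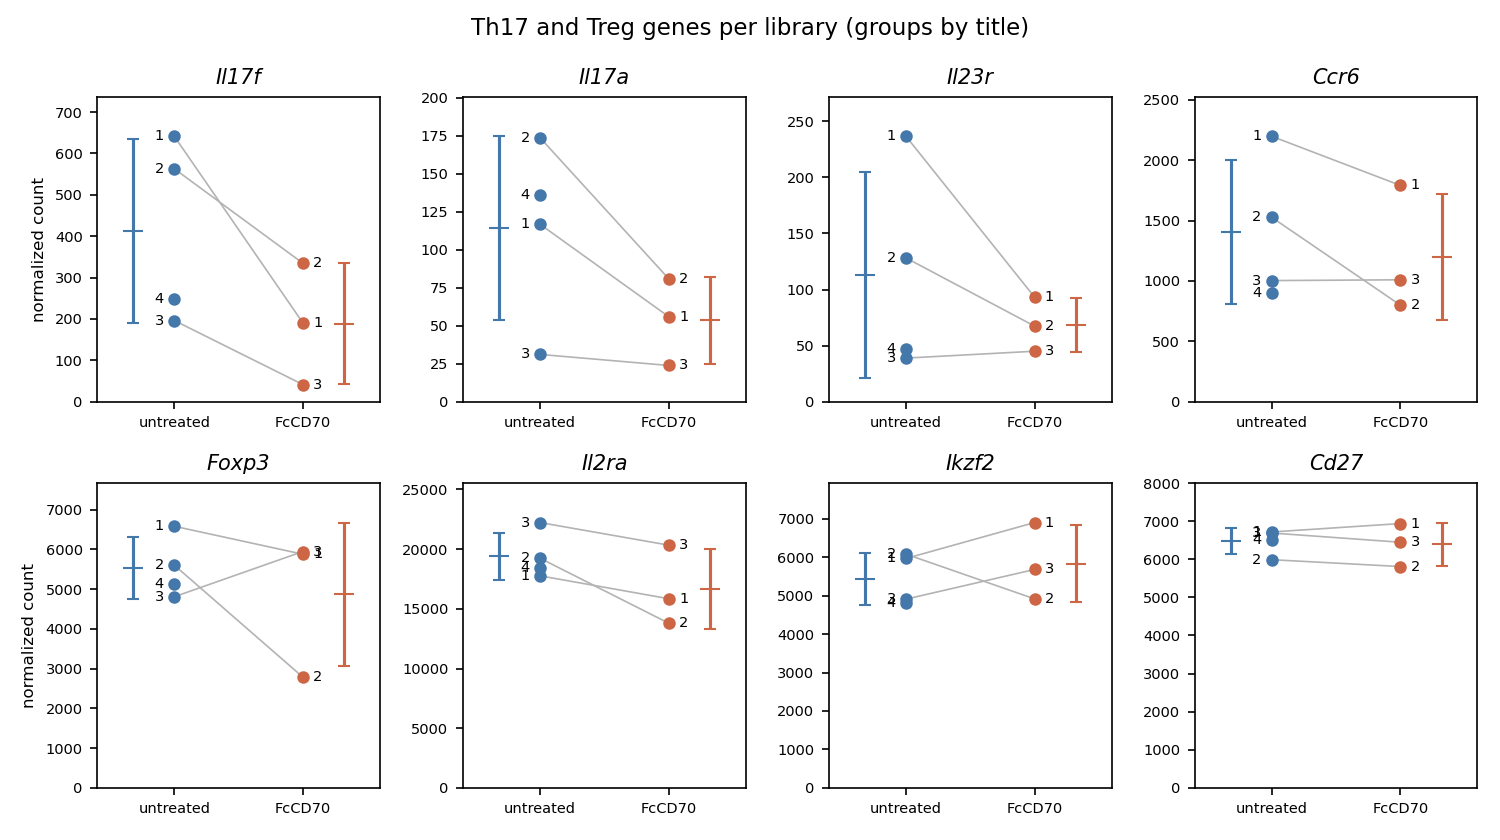
Normalized counts (y axis, from 0) of 8 genes in each of the 4 untreated and 3 FcCD70 libraries, grouped by title; digits are replicate numbers, grey lines join libraries of the same number, and the bars beside the points are the mean ± SD. Il17f and Il17a were lower with FcCD70 in 3 of 3 pairs, whereas Foxp3 was lower in 2 of 3 pairs and lowest in the FcCD70 library numbered 2.

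Genes of the Treg signature lay on both sides of 0. Of the 27 measured members of the Treg signature 16 lay above and 11 below 0, the median log2 fold change was 0.05, and the list did not pass camera (adjusted p = 0.685). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) had 5532 ± 774 (SD, n = 4) normalized counts untreated and 4872 ± 1805 (SD, n = 3) with FcCD70, with a log2 fold change of -0.29 (95% interval -0.77 to 0.19). The single low value, 2788, belonged to the FcCD70 library numbered 2, and without this library, with the covariate, the log2 fold change was 0.11. Il2ra, the high-affinity IL-2 receptor chain, had a log2 fold change of -0.26 (95% interval -0.59 to 0.08), and the inhibitory receptor gene Ctla4 one of -0.09 (95% interval -0.40 to 0.22). Ikzf2, which encodes the Treg factor Helios, had one of 0.04 (95% interval -0.28 to 0.36). Nrp1, a surface marker of thymus-derived Tregs, had the smallest p of the list, with a log2 fold change of 0.34 (95% interval 0.07 to 0.61) and higher values in 3 of 3 pairs.

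Transcripts of CD27 itself and of its signalling family showed no difference past the threshold. Cd27 (ENSMUSG00000030336, chromosome 6, 125232622 to 125237010) had 6477 ± 338 (SD, n = 4) normalized counts untreated and 6397 ± 566 (SD, n = 3) with FcCD70. The list of TNF receptor superfamily and TRAF genes had 23 measured members with a median log2 fold change of -0.02, and Tnfrsf14 had its smallest p (log2 fold change -0.34). Tnfrsf14 had 629 normalized counts in the FcCD70 library numbered 2, against 1437 and 1306 in the other FcCD70 libraries and 1241 to 1458 untreated, and its log2 fold change was 0.04 without that library. In the list of NF-kB pathway genes and targets 17 of 24 members lay above 0 and the median was 0.06. Bcl2l1, an anti-apoptotic gene and the member with the smallest p there and in the list of apoptosis and survival genes (20 members, median -0.01), had 922 ± 35.4 (SD, n = 4) untreated and 725 ± 41.4 (SD, n = 3) with FcCD70. None of these lists passed camera (adjusted p between 0.554 and 0.774), although the NF-kB list passed as higher with 8 libraries less the FcCD70 library numbered 2 (adjusted p = 0.0114), a fit chosen after the data were seen. It did not pass with all 8 and the block (adjusted p = 0.108) or with an estimated correlation over 7 libraries (adjusted p = 0.847).

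Cell cycle genes were lower in the FcCD70 libraries, mostly in 1 pair. Of 25 measured members 23 lay below 0, the median log2 fold change was -0.22, and the list passed camera (adjusted p = 3.36e-05; adjusted p = 0.847 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. The median difference was -0.46 between the libraries numbered 1, -0.07 between those numbered 2 and -0.02 between those numbered 3. Between those numbered 4, with the rebuilt FcCD70 library, it was -0.145. Without the libraries numbered 1 the call was lost (adjusted p = 0.839, median -0.04). A fit of all 7 libraries without the block also lost the call (adjusted p = 0.342, median -0.14), and there the median lay above 0 without the untreated library numbered 1 (0.04) or the FcCD70 library numbered 3 (0.10). These fits do not balance the numbers 1 and 2 against 3 and 4 between the groups. Rrm2, a subunit of ribonucleotide reductase, had 1242 ± 560 (SD, n = 4) normalized counts untreated and 1038 ± 338 (SD, n = 3) with FcCD70, and Top2a and Mki67, genes of dividing cells named after their values were seen, had log2 fold changes of -0.30 and -0.43.

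Across the transcriptome no gene passed the threshold with limma. Of 11083 genes tested with limma, 0 had an adjusted p under 0.05, and 188 had an unadjusted p under 0.05 (122 lower and 66 higher in the FcCD70 libraries), fewer than the 554 that chance alone would give. The edgeR test on the recovered reads of the 7 libraries called 0 genes (173 at an unadjusted p under 0.05). DESeq2 on the same reads called 1, which was Il17f (149 at an unadjusted p under 0.05). The authors' deposited table, over 8 libraries, holds 0 (213 of 14728), and the DESeq2 refit to 8 libraries with the number as a term called 0. Without the FcCD70 library numbered 2, which stood apart from the other libraries, a fit with the numbers 1 and 2 against 3 and 4 as a covariate called 6 genes. These were Il17f, Pim2, Myo6 and Rpl39, with log2 fold changes of -2.02, -0.34, -0.66 and -0.32, and Sorcs2 and Kif1b, with 0.72 and 0.34. This fit and these names other than Il17f were chosen after the values were seen. Leaving out both libraries numbered 2 in the block fit called 19 genes, and leaving out those numbered 3 called 6. Those block fits rest on fewer pairs, with 1 residual degree of freedom.

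The remaining T cell lists did not pass camera, with adjusted p between 0.0963 and 0.815. The list of IL-2 and STAT5 response genes had a median of -0.14 with 13 of 16 members below 0, and Bcl2, a survival gene, led it (had its smallest p) with a log2 fold change of -0.33. This list lay below 0 in 3 of 3 pairs and passed as lower with the rebuilt eighth library (adjusted p = 0.00301) and with the length and GC content trend removed (adjusted p = 0.0406). In fits without the block it passed without the untreated library numbered 1 (0.0166) or 2 (0.0282) or the FcCD70 library numbered 3 (0.00588). Those fits do not balance the numbers 1 and 2 against 3 and 4 between the groups. With an estimated correlation over 7 libraries the IL-2 and STAT5 list did not pass (adjusted p = 0.847). Cytokines and chemokines had a median of -0.17 over 17 members, again led by Il17f, which alone passed when adjusted over the list alone, and the list passed as lower without the libraries numbered 1 (adjusted p = 0.0158) or 2 (adjusted p = 0.0311). With all 7 libraries it did not pass (adjusted p = 0.143, and 0.847 with an estimated correlation). Il21, a cytokine of follicular helper cells that the Th17 list also holds, led the Tfh list (10 members, median -0.03) with a log2 fold change of -0.51. In the list of naive and central memory genes (15 members, median 0.07), Il7r, the IL-7 receptor chain, had 6786 ± 1083 (SD, n = 4) untreated and 8796 ± 1989 (SD, n = 3) with FcCD70, higher in 3 of 3 pairs. Over all genes Il7r passed limma only without the libraries numbered 2, with the block (adjusted p = 1.65e-05), a fit that rests on the pairs numbered 1 and 3. Its DESeq2 adjusted p in the authors' deposited table was 0.287. The chemokine receptor Ccr3 led the list of chemokine receptors and adhesion genes (24 members, median -0.03) with a log2 fold change of 0.88, Tigit led the inhibitory receptors (11 members, median -0.00444) with 0.37, and Gata3 led the Th2 program (9 members, median 0.12) with 0.31. Prf1 led the Th1 and cytotoxic program (19 members, median 0.02) with -0.41, Id2 the TGF-beta response (13 members, median 0.06) with 0.17, Gbp2 the interferon-stimulated genes (18 members, median -0.02) with -0.21, Trbc2 the T cell receptor complex (17 members, median 0.05) with 0.22 and Egr1 the immediate early and stress genes (15 members, median 0.09) with 0.20. The median and the camera direction differed in sign for the inhibitory receptors, and the median and the mean for the Th1 and cytotoxic program.

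Lists of respiration and ribosome genes turned with 1 library. Oxidative phosphorylation genes had a median of 0.10 over 23 members (adjusted p = 0.0963), led by Uqcrfs1 (log2 fold change 0.30), and ribosomal protein genes 0.10 over 21 members (adjusted p = 0.143), led by Rps27a (0.22). Between the libraries numbered 2 these medians were 0.53 and 0.65, and between those numbered 1 they were -0.08 and -0.24. Without the FcCD70 library numbered 2 both lists turned, to -0.07 (adjusted p = 0.00292) and -0.17 (adjusted p = 3.76e-10) by camera with the covariate. Both passed as higher in fits with the block that left out the libraries numbered 1 (adjusted p = 0.00455 and 0.000179) or 3 (adjusted p = 0.0156 and 0.0234), and both as lower without those numbered 2 (adjusted p = 0.0106 and 1.52e-05). Neither call of the fit with the covariate held with an estimated correlation (adjusted p = 0.593 with an estimated correlation for each), nor did either list pass with one over 7 libraries (adjusted p = 0.847). Glycolysis genes had a median of -0.02 over 14 members, with Hk2 at -0.38, and cholesterol synthesis genes one of -0.03 over 22 members. Neither passed camera (adjusted p = 0.774 and 0.348), but the latter passed as lower without the libraries numbered 2 (adjusted p = 0.0147). With an estimated correlation over 7 libraries it did not pass (adjusted p = 0.847). The 1 measured mitochondrially encoded gene, mt-Nd6, had a log2 fold change of 0.03.

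Markers of other cell types were low apart from Ighm, the IgM heavy chain gene, at a mean of 1697 RPM (reads scaled to library size) over the 7 libraries. The B cell list (6 members, median 0.05, mean -0.05) did not pass camera (adjusted p = 0.630), and Cd79b, a B cell receptor component, stood at 7.96 RPM (named after its value was seen). Ms4a1, the gene of CD20, had the list's smallest p (log2 fold change -1.22). The 3 tested CD8 T cell markers of 5 with a row, Klrd1, Eomes (also in the Th1 list) and Cd8b1, lay above 0 and passed camera (adjusted p = 0.0434; adjusted p = 0.847 with an estimated correlation), with a median of 0.82 between the libraries numbered 2. Cd8a and Gzmk (named after their values were seen) fell below the filter, at means of 0.313 and 0.0182 RPM. Cd8a had 0 to 0.638 RPM untreated and 0.128 to 0.416 with FcCD70. Klrd1 had a log2 fold change of 0.37, Cd8b1 one of 0.22, and Eomes 9.61 and 19.5 mean normalized counts untreated and with FcCD70, the latter pair of genes named after their values were seen. The call was lost without the FcCD70 library numbered 2 (adjusted p = 0.317, with the covariate). Myeloid and dendritic cell markers (4 members, led by Cd68 at -0.51, median 0.08 against a negative camera direction) and natural killer and gamma-delta T cell markers (2 members, led by Klrc1 at -0.69) did not pass (adjusted p = 0.927 and 0.815). Erythroid and platelet markers had at most 0.0850 RPM in any of the 7 libraries, and the sex-linked list had no row in the table used here.

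Libraries parted by replicate number rather than by group on the first component. This component, with 40.3% of the variance over 9845 genes, parted the libraries numbered 1 and 2 from those numbered 3 and 4 in both groups, and the second, with 33.9%, set the FcCD70 library numbered 2 apart. Libraries numbered 1 and 2 held 18159685 to 19715108 reads and those numbered 3 and 4 held 21200214 to 23527899. Within the numbers 1 and 2 the Th17 median was below 0 in both pairs, and the other set holds 1 pair with both columns, also below 0, as given above.

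**Figure D2:**
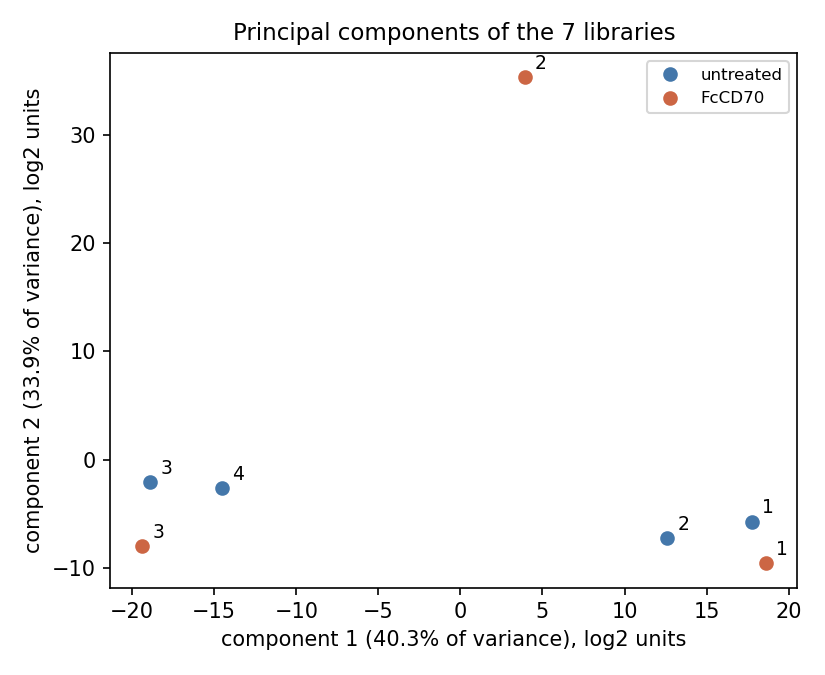
The first (x axis) and second (y axis) principal components of log2(normalized count + 1) over 9845 genes in 7 libraries, coloured by titled group and marked by replicate number. Libraries numbered 1 and 2 lie right of 0 and those numbered 3 and 4 left of 0, and the FcCD70 library numbered 2 lies alone at 35.3 on the second component.

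**Figure D3:**
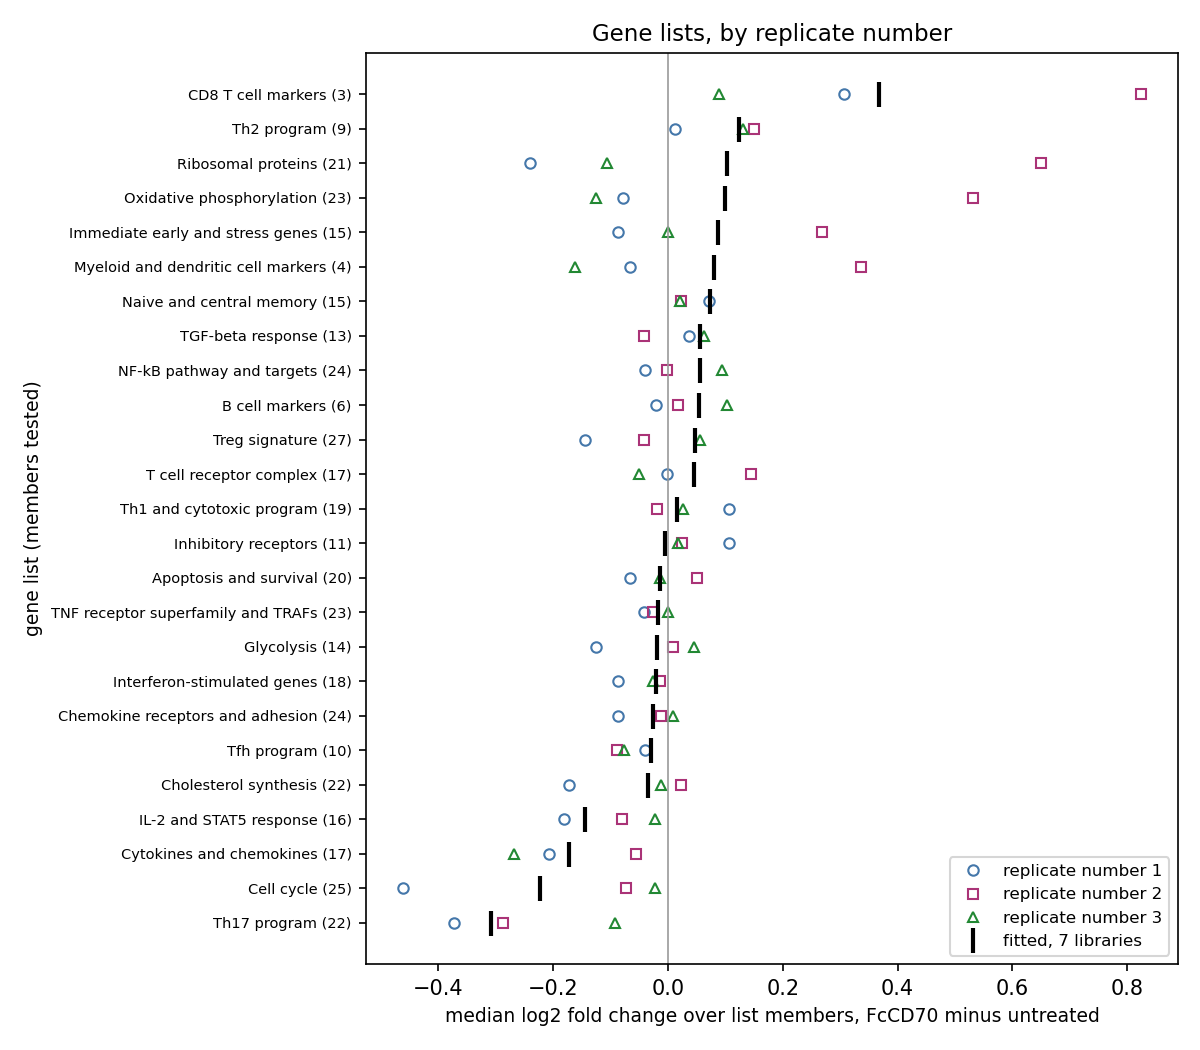
Median log2 fold change over the members of each gene list with at least 3 tested members (x axis, FcCD70 minus untreated, members tested in parentheses), for each same-numbered pair (open symbols) and in the fit over 7 libraries (black bars). The Th17 list lies below 0 in 3 of 3 pairs, and ribosomal protein and oxidative phosphorylation genes lie far above 0 in the pair numbered 2 and below 0 in the other pairs.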

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

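The test of depth, those of length and GC content, and the counts of other splits were set before their results were seen. The tests of other cell types and of leaving out the FcCD70 library numbered 2 were chosen after. Of 78 quantities in the 4 untreated libraries, 4 had a library far from the others, and chance would give about 3.9. Ms4a1, the CD20 gene, had 75.9 normalized counts in the untreated library numbered 1 and 15.5 to 20.02 in the other 3 (gap over range 0.926). The naive and central memory list summed to 8285 RPM in the untreated library numbered 2 and 7736 to 7747 in the other 3 (0.980). The 10 most abundant genes took 4.68% of the reads in the untreated library numbered 1 and 4.26 to 4.33% in the other 3 (0.840). Il22 had 3.48 normalized counts in the untreated library numbered 4 and 0 in the other 3, for a ratio of 1.

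The FcCD70 library numbered 2 stood apart on the second component, with long transcripts low in it. Examples chosen after their values were seen are Med12 at 2384 normalized counts against 8360 and 8765 in the other FcCD70 libraries, and Lyst at 946 against 3557 and 3692. Its deviation from the other libraries correlated across genes with transcript length at a Spearman coefficient of -0.575 (genes are not independent replicates), against at most 0.339 in size elsewhere, which is consistent with a length bias in RNA or library preparation. The tables argue against GC content (coefficient -0.133), and no biological explanation was tested. Reads from other cell types stay open, although the cells were sorted as Tregs from FOXP3-GFP reporter mice, a step that would remove such cells: their markers summed to 1887 RPM, inside the range of 1729 to 1970 elsewhere, but 91.5% of it was Ighm, and the myeloid, CD8 and natural killer sums were the highest of the 7 libraries (83.9, 43.2 and 4.78 against at most 73.2, 39.2 and 4.51). Most of the myeloid sum was Cst3 and Cd74, at 52.0 and 21.7 RPM, inside their ranges elsewhere (29.2 to 52.2 and 9.93 to 23.1). Cd8a stood at 0.275 RPM in this library against up to 0.638 elsewhere, while Klrd1, Cd8b1 and Eomes were highest in it.

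The libraries numbered 1 and 2 parted from those numbered 3 and 4 in both groups. Among genes chosen after their values were seen, Kit had 299.7 to 627 normalized counts in the former and 75.0 to 93.2 in the latter, and Thy1 had 4859 to 6072 and 12236 to 12740. Thinning every library to 18159685 reads left 100.5% of the gap on the first component, and removing the trend on length and GC content left 94.7%, so the tables argue against depth and that trend as the whole cause. Summed markers of other cell types did not overlap between the sets, with means 1.08 times apart, nearly all of it Ighm, and this explanation stays open, as does a batch of mice, cells or culture, which the labels do not give.

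The Th17 list's lower values in the FcCD70 libraries did not rest on the library numbered 2 alone, since without it, with the covariate, the median was -0.19 (adjusted p = 0.00134; adjusted p = 0.593 with an estimated correlation), but in fits without the block the call was lost without the untreated library numbered 1 or the FcCD70 library numbered 3 (adjusted p = 0.215 and 0.561). Those fits without the block do not balance the numbers 1 and 2 against 3 and 4 between the groups. The lost calls cannot be told apart from the difference between these sets. With the block and the preset correlation, the call stayed when the libraries of any 1 number were left out (camera adjusted p at most 0.00624). Without those numbered 1, 2 or 3 the block fit rests on fewer pairs. With the length and GC content trend removed the median was -0.27 (adjusted p = 2.32e-05), which argues against that trend as the whole cause. The block fits 32 of 35 splits, but the untreated library numbered 4 has no partner, so the real split shares its fit with 1 other and the splits are too few for a share under 0.05 (least 0.0625), a limit worked out after the counts were seen. As large a median in size came from 8 of 32 splits, with 0.31 for the real one and at most 0.37 for others, but apart from the 1 with the real fit those others part fewer pairs and hold the real difference of the pairs they part, so they are no chance groupings. An effect of FcCD70 may remain as a hypothesis, with its direction resting on the titles.

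The same splits are too few for the other results. For the cell cycle list 10 of 32 gave a median as large (real 0.22, highest other 0.46), for the CD8 markers 18 (real 0.37, highest other 0.82) and for the number of lists called 16 (real 3, highest other 5). The highest others for both lists part 1 pair each, the numbers 1 and 2, and hold its real difference. For genes past the threshold it was 32 (real 0, highest other 2307), which a real count of 0 fixes in advance, so that this share tests nothing, and for genes at an unadjusted p under 0.05 it was 20 (real 188, highest other 3703). The 4 splits with 2307 genes share 1 fit, in which the pair numbered 2 is the only one parted, so that the FcCD70 library numbered 2, which stands apart, is in effect set against 1 library; this points to a structure of the samples and was not tested further. Without the block, the split of numbers 1 and 2 against 3 and 4 called 457 genes and the real split 0. The highest count, 630, came from the split that differs in setting the FcCD70 library numbered 2 with the numbers 3 and 4.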

How the results depend on the processing

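Nothing in the labels says that the replicate numbers pair samples, and the data do not settle it. Same-numbered deviations correlated at 0.44, -0.04 and 0.53, and the FcCD70 library numbered 1 correlated best with the untreated library numbered 2 (0.46). Without the replicate block 0 genes passed and 1 list, Th17, was called; the cell cycle list had an adjusted p of 0.342 and the CD8 markers one of 0.0621.

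Genes past the threshold were 0 with limma in the other alternatives, except as follows; edgeR, DESeq2, 8 libraries, the covariate and the trend removal were chosen after seeing the data. DESeq2 on 7 libraries called 1 gene, Il17f, which was 1 list member, as did removal of the length and GC content trend. With the covariate and without the FcCD70 library numbered 2 there were 6 genes and 2 list members, and with 8 libraries less that library 4 genes, 1 list member and 7 called lists. Adjusting over the list alone called 1 member. Leaving out replicates gave 0 to 19 genes, 0 to 5 list members and 1 to 6 called lists, against 3.

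With an estimated correlation 0 lists were called, and the Th17, cell cycle and CD8 lists each had an adjusted p of 0.847. The adjustment gave many lists this same value. Before adjustment the Th17, cell cycle and CD8 lists had camera p of 0.0495, 0.320 and 0.171. Their estimated correlations were 0.0298, 0.63 and 0.43, against the preset 0.01. For the oxidative phosphorylation and ribosomal protein lists the estimates were 0.93 and 0.97. Without the FcCD70 library numbered 2, with the covariate and an estimated correlation (chosen after seeing the data), 0 lists were called. The Th17, cell cycle and CD8 lists each had 0.593 there. Leaving out replicates, with or without the block, gave adjusted p from 1.42e-05 to 0.561 for Th17, from 4.73e-06 to 0.915 for cell cycle and from 0.00793 to 0.403 for the CD8 markers. The lowest value for Th17 came without the untreated library numbered 4, which with the block does not enter the fold changes. With the block the highest value for Th17 was 0.00624. The cell cycle direction turned without the untreated library numbered 1 (0.614) or the FcCD70 library numbered 3 (0.585). Those fits had no block and did not balance the numbers 1 and 2 against 3 and 4 between the groups. The CD8 call, on 3 genes, was also lost with ranks (0.0617), a background of means of at least 50 (0.161, 2 genes), no filter (0.222, 5 genes), the covariate without the FcCD70 library numbered 2 (0.317, or 0.308 with 8 libraries) and the trend removed (0.157). The causes were not tested. Of 1077 values of 47 named genes under alternatives, 82 in 24 genes changed sign and 6 passed the threshold. The median 95% interval reached 0.36 on the log2 scale to each side, which limits what could be detected.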

Other observations

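Genes outside the fixed lists also lay on 1 side in all 3 pairs without passing the threshold, and the examples given were chosen after their values were seen. With only 3 pairs, many genes lie on 1 side in all of them by chance, so a count of pairs alone is weak evidence. Rad51b, a recombination gene, had 16.5 to 48.4 normalized counts in the untreated libraries and 0, 0 and 2.65 in the FcCD70 libraries, and in the authors' deposited table it shared the smallest adjusted p, 0.211, with Il17f. Gucy1b3, a subunit of soluble guanylate cyclase, had 26.7 ± 6.19 (SD, n = 4) untreated and 73.5 ± 13.2 (SD, n = 3) with FcCD70, and its ranges did not overlap.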
